A study of Homo sapiens with 3 samples.

How the data were processed

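Jurkat cells, an established T-lineage leukaemia line, were grown for 48 hours without addition, with 50 mM sodium oxamate, or with 50 mM sodium oxamate and 10 mM L-sodium lactate, per the labels' protocols. Total RNA was taken with TRIzol from equal numbers of cells, a diluted ERCC spike-in mix was added to it, polyadenylated RNA was selected, and libraries were made with a kit that does not mark strand, per the labels' protocols. FastQC 0.11.9, STAR 2.7.1a, HTSeq 0.11.2 and the genome build hg19 are named in the submitters' processing notes, with no role or order. The annotation, the filter on genes and the normalization are not given in the sources used here.

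The authors deposited 1 table of values called normalized counts, with 17365 rows and 1 column per library. All values are whole numbers, so they were treated as a score made by the authors from read counts and rounded after normalization, and not as raw counts. No count model was fitted, whole reads could not be recovered, and the depth in reads is unknown. The sums over genes are 8220199 for control, 8821115 for oxamate and 8171633 for oxamate+lactate. The median value per gene is 177, 181 and 174, and the 10 highest genes hold 5.76%, 5.16% and 5.64% of the sum. The 36 ERCC rows hold 0.368%, 0.342% and 0.353% of the sum, were left out of the gene counts and served to describe the technical spread. Normalization can absorb or leave a global difference in RNA per cell, and a factor shared by all genes of a library shifts all its ratios, so counts are also given relative to the median ratio of all genes.

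Samples were grouped by their treatment label, 1 library per condition and 3 in all. The 3 pairs of libraries were compared as log2((value + 1)/(value + 1)) for the 12292 genes whose mean over the 3 libraries was at least 50. The pseudocount of 1 makes the ratio of low genes slightly too small. Genes at least 2-fold higher or lower were counted. With 1 library per condition there is no test, p-value or standard error. Nothing says how many cultures stand behind each library.

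Of 34 gene lists written before the data were examined, 28 had at least 5 genes over the floor. For each, the median log2 ratio was set among those of 10000 random lists of the same size, matched on mean value in 20 bins, and a list was said to stand apart when it fell outside their central 95%. This describes these libraries, with 84 such comparisons (28 lists in 3 comparisons), and is no test of the conditions. Named genes were chosen by a rule fixed in advance. It takes protein-coding and other named genes over the floor whose highest value is at least 100, with the 10 highest and 10 lowest ratios of oxamate against control, the 6 at each end of oxamate+lactate against oxamate and the 4 at each end of oxamate+lactate against control. To these it adds the 4 leading members of each list that stood apart and 9 genes named in advance, among them LDHA, LDHB, EP300, MYC and NOTCH1. The rule gave 114 genes, and the text gives those that best describe each list. Some of the genes the rule named are not reported here. Genes under the floor named in the closing section were chosen after their values were seen.

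The return toward control is the share of the log2 ratio of oxamate against control that is absent in oxamate+lactate against control, over the 2-fold genes. To show what chance gives, 100 sets of 3 libraries were simulated around the deposited values with counting noise and with assumed coefficients of variation of 0.1 and 0.2. The same was done for the overlap of the 2 comparisons that share the control library. The deposited values were taken as counts there, so these levels are approximate. After the results were seen, 20 sets per noise level were also simulated to count the lists that stand apart in 2 comparisons, with 1000 random lists in each. Noise was drawn for each gene alone. The test of control RNA in the oxamate+lactate library was first written to decide on the percentile of the lipid median alone. Since those lists were picked from the data, it now also demands that the lowest lipid gene lies above the median of the other genes, which it did not.

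Gene type, GC content, length of the longest transcript and overlap with coding genes came from GENCODE 29, which is on another build than the files, so no coordinates are given. Of the gene rows, 14380 were matched by name or by synonyms in a RefSeq table of assembly GRCh38.p14, and 91.2% of the genes over the floor had a GC content and length. HTSeq's handling of overlapping genes is not known, so leading genes that overlap others are marked where they are named in the report. RAG1 (overlapping RAG2), HSP90AA1 (WDR20), ACACA (C17orf78), SREBF1 (RAI1) and MT-CO3 (MT-ATP6) overlap others as well.

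The computation was tested on simulated libraries with a coefficient of variation of 0.1. For oxamate against control it called 45 of 45 genes lowered 4-fold and 50 of 50 raised 4-fold, 96.0% of 50 genes raised 2.5-fold and 79.2% of 48 genes lowered to 0.4-fold, with 6 of 12086 unchanged genes called. A first version of this test demanded more than 80% recovery at each size, which the 0.4-fold genes missed. That demand was replaced by one on the median ratio, which has to lie within 0.1 of the simulated fold after allowing for the library sums. A simulated return of 30% was measured as 32.1% over 193 genes, and 3 of 100 random lists of unchanged genes fell outside the central 95%.

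Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, floors of 10, 200 and none, fold thresholds of 1.5 and 4, scaling by the median ratio, by equal sums, by a trimmed mean of the ratios and by equal ERCC sums, the mean of a list in place of its median, and 5 matching bins. Removal of a quadratic trend on GC content and length, shares on the linear scale, and the amino acid response list without its 4 lowest members were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.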

Results

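Polyadenylated RNA was sequenced from Jurkat cells, a human T-lineage acute lymphoblastic leukaemia line, grown for 48 hours in 3 media. The control culture had standard medium, the oxamate culture had 50 mM sodium oxamate, an inhibitor of lactate dehydrogenase, and the oxamate+lactate culture had 50 mM sodium oxamate with 10 mM L-sodium lactate. The series set out to relate lactylation of histone H3 at lysine 18, a mark that depends on lactate, to transcription. Oxamate against control was taken to address a lower supply of lactate, and oxamate+lactate against oxamate its replacement. These RNA values measure neither lactate nor the mark. Each condition had 1 library, so no difference below has a replicate check and no p-value was computed. "Higher" and "lower" compare libraries, on the log2(value + 1) scale.

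The values are normalized read counts as deposited, for 17329 genes and 36 ERCC spike-in RNAs. They summed over genes to 8220199 in control, 8821115 in oxamate and 8171633 in oxamate+lactate, and the ERCC rows summed to 30327, 30255 and 28951. The number of reads behind each library is not given in the sources used here, so the depth is unknown and no counting interval is given. The 18 ERCC RNAs with a mean of at least 100 had a median log2 ratio of 0.00 (SD 0.13) for oxamate against control, -0.08 (SD 0.11) for oxamate+lactate against oxamate, and -0.08 (SD 0.19) for oxamate+lactate against control. Over the 12292 genes with a mean of at least 50, the medians were 0.08 (SD 0.38), -0.09 (SD 0.19) and -0.01 (SD 0.31). The ERCC spread measures handling after RNA extraction, and not the spread between cultures.

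In the oxamate library, genes of the amino acid response and targets of ATF4, the transcription factor that drives amino acid synthesis and import when amino acids are short, were lower than in control. Of 29 genes of this list over the floor, 27 lay below the median of all genes, 17 were at least 1.5-fold lower and 8 at least 2-fold lower. The list median was -0.66, against 0.11 for random lists of the same expression level (percentile 0 of 10000 random lists). ASNS, asparagine synthetase, had 1327 normalized counts in control and 312 in oxamate (log2 ratio -2.09). TRIB3, a pseudokinase induced by ATF4, had 2282 and 601 (-1.92). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, had 1331 and 389 (-1.77), and the transcription factor ATF5 had 3713 and 859 (-2.11). PCK2 and ATF5 overlap other coding genes in the annotation (NRL for PCK2, IL4I1 and NUP62 for ATF5), and the library kit does not mark strand, so reads of such neighbours cannot be told apart. The lowest ratio of the named genes was that of ASS1, which is not in this list. It encodes argininosuccinate synthase, an enzyme of the route from citrulline to arginine, and had 3011 in control and 439 in oxamate, 6.85-fold lower.

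Regulators of T-lineage identity were higher in oxamate than in control. The T-ALL transcription factor list had a median of 0.48 (random lists 0.11, percentile 100), with 14 of 17 genes above the median of all genes. TCF7, which encodes the T-cell factor TCF1, had 3013 normalized counts in control and 6269 in oxamate (1.06; TCF7 overlaps SKP1). IKZF1, encoding Ikaros, had 2955 and 5335 (0.85), BCL11B had 1771 and 2988 (0.75), and NOTCH1, the receptor most often mutated in this leukaemia, had 1352 and 2327 (0.78). Targets of NOTCH1 had a median of 0.76 (random lists 0.08, percentile 100), with 7 of 10 at least 1.5-fold higher. Among these, TRIB2 had 264 and 542 (1.03), HES1, the Notch effector repressor, had 55 and 98 (0.82), and MYC had 2739 and 5299 (0.95). Of the other targets, HES4 had 371 and 413 (0.15), and the lowest was at -0.16. TAL1, a T-ALL oncogene, had 906 and 1133 (0.32).

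Immediate early and T-cell activation genes were also higher in oxamate, with a list median of 0.57 (random lists 0.07, percentile 100). Of the 32 genes listed, 16 were over the floor. Of these 16, 15 lay above the median of all genes and 3 were at least 2-fold higher. The exception was the activation marker CD69, at 83 and 78 (-0.09). EGR1, an early growth response factor, had 85 normalized counts in control and 636 in oxamate, 7.41-fold higher. KLF2, a factor of T-cell quiescence and trafficking, had 446 and 1922 (2.11), and DUSP2, a phosphatase of MAP kinases, had 132 and 399 (1.59). Markers of the T-cell receptor complex and T lineage had a median of 0.30 (random lists 0.11, percentile 99.7), but the members went both ways. CD1A, a marker of cortical thymocytes, had 230 and 683 (1.57), CD1E had 67 and 157 (1.22), and DNTT, the terminal transferase of immature lymphocytes, had 1033 and 1950 (0.92). RAG1, a recombinase subunit, had 2816 and 1795 (-0.65). Once the trend of the ratios on GC content and transcript length was removed, the call of this list was lost (percentile 73.5), and so it was with the mean of the list in place of its median.

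**Figure D1:**
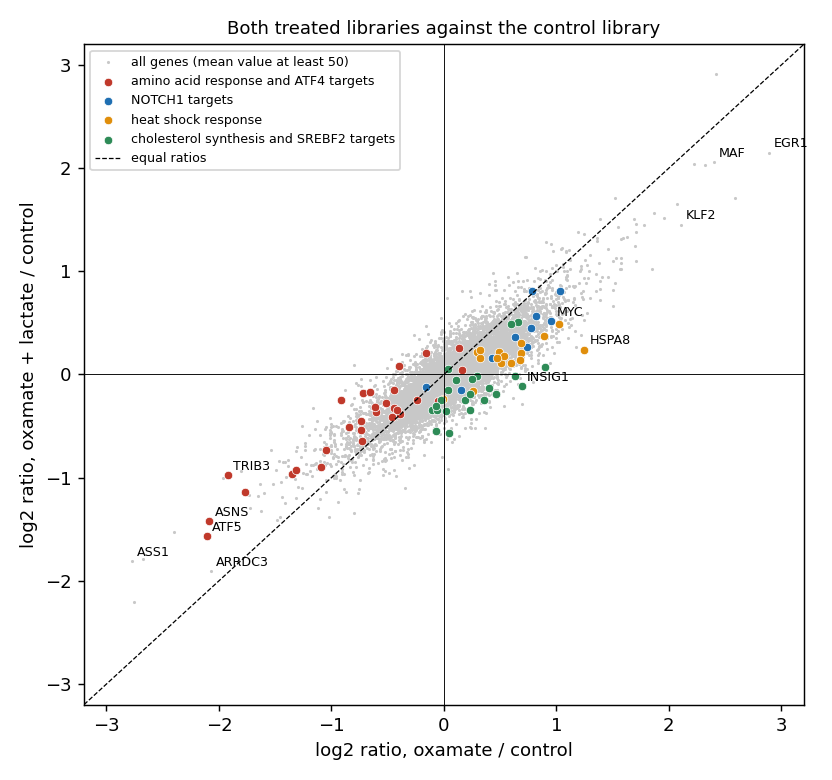
Log2 ratio of oxamate over control (horizontal axis) against log2 ratio of oxamate+lactate over control (vertical axis), 1 point per gene with a mean normalized count of at least 50 (12292 genes, 1 library per condition), with 4 gene lists in colour and a dashed line at equal ratios. ASNS lies at -2.09 and -1.42 and EGR1 at 2.89 and 2.15, both nearer to 0 on the vertical axis than on the horizontal one.

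Chaperone genes were higher in oxamate. The heat shock list had a median of 0.52 (random lists 0.12, percentile 100), with 15 of 16 genes above the median of all genes and 7 at least 1.5-fold higher. HSPA8, the constitutive cytosolic HSP70, had 5996 normalized counts in control and 14220 in oxamate (1.25), its co-chaperone DNAJA1 had 1185 and 2415 (1.03), and HSP90AA1 had 10851 and 20138 (0.89). Chaperones of the endoplasmic reticulum had a median of 0.29 (random lists 0.11, percentile 98.6), with HSPA5, which encodes BiP, at 1767 and 3325 (0.91). This call was lost with the mean of the list in place of its median. The MYC and ribosome biogenesis list had a median of 0.30 (random lists 0.11, percentile 99.7), and 23 of 31 genes lay above the median of all genes. Besides MYC, POLR1C had 235 and 453 (0.94; it overlaps XPO5) and the nucleotide kinase NME1 had 146 and 242 (0.73; it shares exons with NME1-NME2).

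Small shifts downward relative to random lists were seen in 5 lists. The median of S phase and DNA replication genes was -0.08 (random lists 0.11, percentile 0), that of nuclear-encoded respiratory chain genes -0.04 (0.10, percentile 0.945) and that of cytosolic ribosomal proteins -0.01 (0.13, percentile 0.01). For polyamine, purine and pyrimidine synthesis it was -0.05 (0.13, percentile 0.64), a call that was lost with the mean in place of the median. In none of these 4 lists was a gene 1.5-fold lower. Examples are MCM6, a subunit of the replicative helicase, at 2559 and 2048 (-0.32), and IMPDH2, of guanine nucleotide synthesis, at 2998 and 2176 (-0.46). The list of MondoA targets, which respond to glucose phosphates, had 8 genes over the floor and a median of -0.21 (0.08, percentile 1.13), a call that was lost with a floor of 200. The arrestin ARRDC3 had 479 and 113 (-2.07), and TXNIP, a brake on glucose uptake, had 748 and 515 (-0.54), while 2 members were at least 1.5-fold higher.

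The remaining lists did not stand apart for oxamate against control. Glycolysis genes had a median of 0.00 (random lists 0.11, percentile 6.97), with none of 21 genes 1.5-fold different. The targets of the inhibitor, LDHA and LDHB, had 4937 and 4952, and 7383 and 7363. Genes of lactate transport and of lactyl or acetyl turnover had a median of 0.14 (percentile 66.6). Of these, EP300, an acetyltransferase also described as a lactyltransferase, had 1164 and 1548 (0.41), and SLC16A1, the lactate transporter MCT1, had 1180 and 1427 (0.27). Pyruvate dehydrogenase and TCA cycle genes were at 0.04 (percentile 13), mitochondrially encoded genes at -0.03 (3.83), HIF-1 targets at -0.09 (5.66), NRF2 targets at 0.08 (36.1) and G2/M genes at 0.08 (22.6). Apoptosis regulators were at 0.13 (77.8), p53 targets at 0.12 (71.7), autophagy and lysosome genes at 0.14 (80.6), interferon-stimulated genes at 0.19 (91.1) and splicing factors at 0.21 (86.5). Cholesterol synthesis genes were at 0.23 (94.8), hyperosmotic response genes at 0.31 (95.1) and fatty acid synthesis genes at 0.09 (39.3).

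Across the 12292 genes, 149 were at least 2-fold higher and 108 at least 2-fold lower in oxamate than in control. Relative to the median of all genes the split was 99 higher and 132 lower, and with columns scaled to equal totals, which moves the median of all genes from 0.08 to -0.02, 86 genes were higher and 146 lower. In libraries simulated with no effect, counting noise alone gave 0.45 higher and 0.03 lower. An assumed coefficient of variation between cultures of 0.1 gave 6.84 and 0.91, below both observed counts, and one of 0.2 gave 249 and 74.8, above the observed higher count and below the lower one. At 0.2 the simulated ratios had a wider SD, 0.435, than the observed 0.382. Besides EGR1 and KLF2, the highest named ratios were those of MAF, a transcription factor, at 36 and 194 (2.40), CEBPE, a myeloid transcription factor, at 21 and 109 (2.32), and SPRN at 32 and 138 (2.07; it overlaps MTG1). They were followed by KCTD11 at 47 and 185 (1.95), RFX8 at 40 and 149 (1.87), ADAT3 at 27 and 100 (1.85; it overlaps SCAMP4) and the cannabinoid receptor gene CNR2 at 136 and 447 (1.71). Besides ASS1, low ratios outside the lists were those of SPNS3 at 1169 and 221 (-2.40), the homeobox gene HOXB9 at 186 and 47 (-1.96; it overlaps HOXB7), AARD at 104 and 28 (-1.86) and MFAP4 at 121 and 34 (-1.80; it overlaps MAPK7). ACTB, beta-actin, had 28202 and 35477 (0.33). The ratios were higher for genes of higher GC content (Spearman correlation 0.31 across 11214 genes, which are not independent replicates). The 2-fold higher genes had a median GC content of 55.9%, the lower ones 49.5% and all genes 48.2%. With the GC and length trend removed, 82 genes were higher and 97 lower. With equal ERCC sums 150 were higher and 100 lower, the direction of the deposited values.

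**Figure D2:**
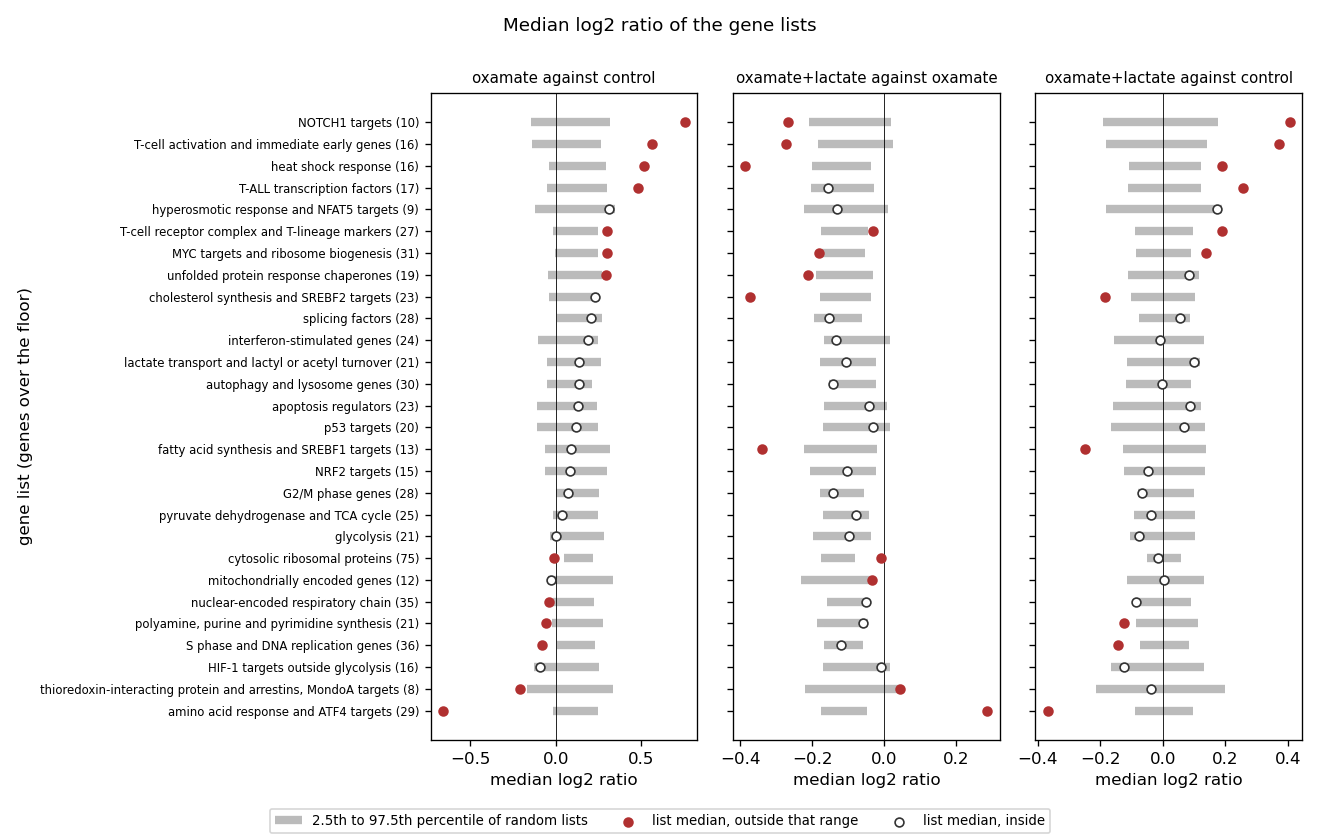
Median log2 ratio (horizontal axis) of the 28 gene lists tested (rows, with the number of genes over the floor) in the 3 comparisons (panels), with grey bars for the central 95% of 10000 random lists matched on mean level, filled points outside that range and open points inside. The amino acid response and ATF4 list lies at -0.66, 0.29 and -0.37 from the left panel to the right one.

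With lactate added to oxamate, lipid synthesis and chaperone genes were lower, and amino acid response genes higher, than with oxamate alone. Cholesterol synthesis genes and targets of SREBF2 had a median of -0.37 (random lists -0.10, percentile 0), and 22 of 23 lay below the median of all genes. INSIG1, a sensor of sterol levels, had 3228 normalized counts in oxamate and 1849 in oxamate+lactate (-0.80), and DHCR7, a reductase of cholesterol synthesis, had 1872 and 1195 (-0.65). Fatty acid synthesis genes had a median of -0.34 (random lists -0.11, percentile 0). FASN, fatty acid synthase, had 7130 and 4098 (-0.80), ACACA, acetyl-CoA carboxylase, had 2451 and 1754 (-0.48), and the desaturase gene SCD had 6017 and 4390 (-0.45). The heat shock list had a median of -0.39 (random lists -0.12, percentile 0). HSPA8, at 14220 and 7073 (-1.01), was the only gene of the 12292 to reach 2-fold lower in the values as deposited. DNAJA1 had 2415 and 1661 (-0.54), HSPH1 1582 and 1095 (-0.53) and HSP90AA1 20138 and 14007 (-0.52).

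Amino acid response genes had a median of 0.29 for oxamate+lactate against oxamate (random lists -0.11, percentile 100), with 27 of 29 above the median of all genes and 4 at least 1.5-fold higher. TRIB3 had 601 and 1159 (0.95), ASNS 312 and 495 (0.66), PCK2 389 and 604 (0.63) and the glycoprotein hormone gene STC2 489 and 773 (0.66). The highest named ratios were those of ASS1 at 439 and 859 (0.97), HOXB9 at 47 and 92 (0.95), TRIB3, ICA1 at 57 and 107 (0.90), MFAP4 at 34 and 63 (0.87) and SPNS3 at 221 and 404 (0.87). Among the lowest were also KCNA6, a potassium channel gene, at 300 and 164 (-0.87; it overlaps GALNT8), and ADAT3 at 100 and 56 (-0.83).

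Besides the heat shock list, 4 lists that stood higher in oxamate than in control stood lower in oxamate+lactate than in oxamate. The oxamate library enters both ratios, which by itself gives opposite directions: across genes they had a correlation of -0.60 and a covariance of -0.0435, against -0.48 and -0.00944 in libraries simulated with no effect and counting noise, and -0.50 and -0.0940 with a coefficient of variation of 0.2. Over all lists, 8 turned in opposite directions, and at most 2 did in each set simulated with 1 common level for both treated libraries and noise independent between genes. Noise shared by the genes of a list was not simulated. Immediate early genes had a median of -0.27 (random lists -0.08, percentile 0.02), with EGR1 at 636 and 381 (-0.74) and KLF2 at 1922 and 1223 (-0.65). NOTCH1 targets had a median of -0.27 (random lists -0.09, percentile 0.15), with DTX1, a Notch pathway regulator, at 732 and 526 (-0.48) and MYC at 5299 and 3922 (-0.43). The MYC and ribosome biogenesis list was at -0.18 (random lists -0.11, percentile 1.21), with NOLC1 at 4196 and 3229 (-0.38). MYC is a member of this list, of the NOTCH1 targets and of the immediate early list, so these lists are not independent. Endoplasmic reticulum chaperones were at -0.21 (random lists -0.11, percentile 0.68), with HSPA5 at 3325 and 2278 (-0.55), a call lost with a floor of 200 and with the mean in place of the median. The T-ALL transcription factors did not stand apart (-0.16, percentile 19.1). NOTCH1 had 2327 and 1716 (-0.44).

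Ribosomal protein genes (median -0.01, percentile 100), T-cell receptor and T-lineage markers (-0.03, percentile 99.0), mitochondrially encoded genes (-0.03, percentile 97.6) and MondoA targets (0.04, percentile 97.6) stood above their random lists, whose medians were -0.12, -0.11, -0.13 and -0.09. The first 3 of these medians changed sign under other scalings of the libraries. A scaling moves random lists as well, so this bears on the sign and not on the call. The call of the mitochondrially encoded genes was lost under other floors and with the GC and length trend removed (excess over random lists 0.0445). That of the MondoA targets was lost under other floors, with a pseudocount of 10 and with 5 matching bins. TXNIP had 515 and 717 (0.48), TRAC, the T-cell receptor alpha constant region, had 482 and 551 (0.19), and the mitochondrial oxidase gene MT-CO3 had 25316 and 29697 (0.23). Lists inside the range of random lists were glycolysis (-0.10, percentile 63.1), lactate transport and lactyl or acetyl turnover (-0.11, 43.9), HIF-1 targets (-0.01, 92.4), the TCA cycle (-0.08, 82.6), the nuclear-encoded respiratory chain (-0.05, 96.9) and the hyperosmotic response (-0.13, 31.8). The same held for NRF2 targets (-0.10, 55.5), G2/M genes (-0.14, 20.2), S phase genes (-0.12, 36), polyamine and nucleotide synthesis (-0.06, 93.5), p53 targets (-0.03, 83.0), apoptosis regulators (-0.04, 79.8), autophagy (-0.14, 4.73), interferon-stimulated genes (-0.13, 9.50) and splicing factors (-0.15, 24.6). LDHA had 4952 and 4648, LDHB 7363 and 7000, SLC16A1 1427 and 1190 (-0.26), and EP300 1548 and 1287 (-0.27).

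Single-gene differences between the 2 treated libraries were small. No gene was 2-fold higher and 1 was 2-fold lower, and relative to the median of all genes 3 were higher and 0 lower. At 1.5-fold, 31 were higher and 111 lower. The SD of the ratios, 0.19, was below the 0.247 that simulated unchanged libraries gave with a coefficient of variation of 0.1, and above the 0.140 of counting noise alone.

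Against control, 9 of the 13 lists that stood apart in oxamate also stood apart, in the same direction, in the oxamate+lactate library. Both comparisons use the 1 control library, so a difference of that culture alone would give such agreement too. Sets simulated with no effect and with noise independent between genes gave at most 2 such lists. On average only 1.45 to 1.6 lists stood apart for oxamate against control in those sets, so few could agree. Amino acid response genes were lower (median -0.37, random lists 0.00, percentile 0), with ASNS at 1327 and 495 (-1.42). ASS1, which is outside that list, had 3011 and 859 (-1.81). NOTCH1 targets (0.41, percentile 100), immediate early genes (0.37, percentile 100), T-ALL transcription factors (0.26, percentile 100), heat shock genes (0.19, percentile 99.8), T-lineage markers (0.19, percentile 100) and MYC and ribosome biogenesis genes (0.14, percentile 99.8) were higher than random lists. EGR1 had 85 and 381 (2.15), MAF 36 and 153 (2.06), CEBPE 21 and 89 (2.03), TCF7 3013 and 5297 (0.81), TRIB2 264 and 463 (0.81), CD1A 230 and 469 (1.02) and MYC 2739 and 3922 (0.52). S phase genes (-0.14, percentile 0.02) and polyamine and nucleotide synthesis genes (-0.12, percentile 0.42) were lower.

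Lipid synthesis genes differed from this. They did not stand apart with oxamate alone (cholesterol synthesis genes did with the mean in place of the median), but with lactate they lay below control, cholesterol synthesis genes at -0.18 (percentile 0.08) and fatty acid synthesis genes at -0.25 (percentile 0.02). HMGCS1, an early enzyme of the mevalonate pathway, had 998 normalized counts in control, 1029 in oxamate and 672 in oxamate+lactate. MVD, also of that pathway, had 829, 789 and 567, the regulators SREBF2 and SREBF1 had 2325, 2226 and 1827, and 3472, 3234 and 2554, and the desaturase gene FADS2 had 4122, 3640 and 2656 (it overlaps FADS1). ELOVL6, an elongase, had 167, 79 and 102. The other lists did not stand apart: glycolysis (-0.08, percentile 6.50), lactate transport and lactyl or acetyl turnover (0.10, 94.6), HIF-1 targets (-0.12, 8.92), the TCA cycle (-0.04, 20.4), the nuclear-encoded respiratory chain (-0.09, 2.81), mitochondrially encoded genes (0.00, 49.1), endoplasmic reticulum chaperones (0.08, 91.6) and the hyperosmotic response (0.17, 96.5). Nor did NRF2 targets (-0.05, 22.5), G2/M genes (-0.07, 4.74), p53 targets (0.07, 86.9), apoptosis regulators (0.09, 92.7), autophagy (0.00, 57), interferon-stimulated genes (-0.01, 53.4), ribosomal proteins (-0.02, 21.4), splicing factors (0.06, 86.2) and MondoA targets (-0.04, 39.7). LDHA had 4937 and 4648.

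In this comparison 67 genes were at least 2-fold higher and 42 lower. Of these, 57 and 31 were also 2-fold higher or lower in oxamate. Independent lists of these sizes would share 0.812 and 0.369 genes. Both comparisons use the same control library, and libraries simulated with no effect shared 0.03 and 0 genes with counting noise, and 41.7 and 7.80 with a coefficient of variation of 0.2. The latter gave ratios against control an SD of 0.435 for oxamate and 0.436 for oxamate+lactate, wider than the observed 0.382 and 0.309. The covariance of the 2 sets of ratios was 0.102 (simulated 0.0100 with counting noise and 0.0952 with a coefficient of variation of 0.2), and their correlation across genes, which are not independent replicates, was 0.87 (simulated 0.51 and 0.50). With 1 control library it could not be split, so part of the excess may come from the shared control.

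**Figure D3:**
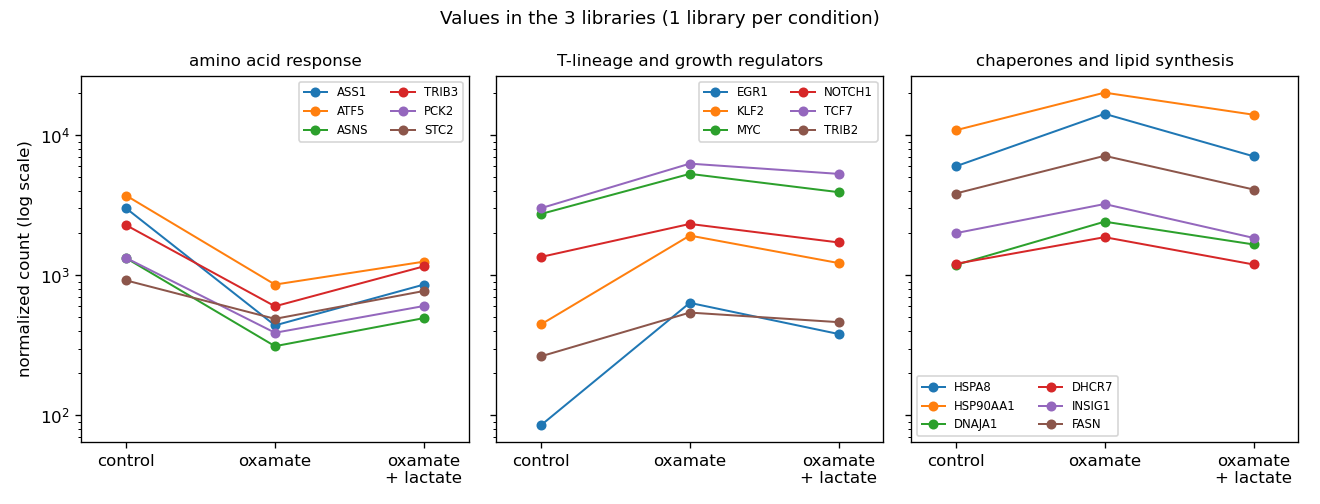
Normalized counts (vertical log axis) of 18 genes in the 3 libraries (horizontal axis, 1 library per condition), with lines joining the values of a gene. The genes on the left, members of the amino acid response list except for ASS1, are lowest in oxamate (ASNS 1327, 312 and 495). The genes shown in the other panels are highest in oxamate (HSPA8 5996, 14220 and 7073). The lipid genes shown are a selection, and neither lipid synthesis list stood apart for oxamate against control.

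To measure the return toward control, the 257 genes at least 2-fold higher or lower in oxamate were followed into the oxamate+lactate library. There, 239 of them (93.0%) lay closer to control, 32 had come at least halfway back on the log2 scale and none had passed the control value. The genes halfway back included HSPA8 (80.9% of its log2 change) and DNAJA1 (52.6%). The median share taken back was 29.1% (interquartile range 18.4% to 40.9%). Since the oxamate library enters both ratios, some return comes by chance: with 1 common level for both treated libraries, counting noise gave a median of 9.32%, and coefficients of variation of 0.1 and 0.2 gave 16.3% and 30.9%. The last value lies above the observed one, but that setting selected 886 genes in place of 257. Its spread is also wider than that of these libraries. In the same order of noise levels, 3.91 of 218, 25.1 of 321 and 254 of 886 simulated genes came at least halfway back. No chance level was computed for the count of genes closer to control. Unchanged libraries simulated at 0.2 had an SD of 0.435 for oxamate against control and for oxamate+lactate against oxamate, where 0.382 and 0.190 were observed. Selecting instead the 109 genes that differed 2-fold between oxamate+lactate and control, the oxamate value lay farther from control in 70 (64.2%), and the median share was 10.8%, while these simulations gave -6.62%, -15.5% and -36.4%.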

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

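The tests of GC content and length, of control RNA in a library and of a list without its lowest members were chosen after the results were seen. The selection of genes on oxamate+lactate against control was fixed before the data were examined, but its use as a test of chance was decided afterwards.

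Cholesterol synthesis genes and SREBF2 targets lay on opposite sides of control in the 2 treated libraries, with a median log2 ratio of 0.23 in oxamate and -0.18 in oxamate+lactate. This difference was not tested, since each condition has 1 library. The first of these medians lies within the range of random lists (percentile 94.8) and the second below it (percentile 0.08).

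Under the floor on the mean, and so outside the comparisons above, 2 genes had a log2((value + 1)/(value + 1)) of at least 2 against control in both treated libraries and a value of at least 40 in one of them. This rule only lists genes and is no estimate of their fold, since the reads behind the low control values are unknown. CD28, the costimulatory receptor of T cells, had 3 normalized counts in control, 66 in oxamate and 20 in oxamate+lactate. MURC had 8, 51 and 36. Both were chosen after their values were seen.

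The lower level of amino acid response genes with oxamate is the first pattern weighed. A GC content or length bias is argued against: with that trend removed the list stayed 0.79 below its random lists (-0.79, percentile 0). The list without its 4 lowest members was still at -0.60 (percentile 0). A difference between cultures other than the treatment, such as cell density or the age of the medium, cannot be told apart from oxamate, because 1 control library leaves no spread between cultures, and an effect of oxamate on the amino acid response stays open and untested.

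The second pattern is the higher level of T-ALL transcription factors, NOTCH1 targets and immediate early genes. GC content or length bias is argued against as the whole cause for these 3 lists, since with the trend removed the smallest excess over random lists was 0.37 (percentile 100). For the T-cell receptor and T-lineage list the excess went from 0.19 to 0.038 and the percentile from 99.7 to 73.5, so its call may come from the trend on GC content. Whether that trend arose in the cells or in library preparation was not tested. A difference between cultures stays open here as well, and so does an effect of oxamate.

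The third pattern is that the oxamate+lactate values lay between oxamate and control. Chance from the oxamate library entering both ratios would, with 1 common level for both treated libraries, put the median share at or below 0 for genes selected without that library, but it was 10.8%, and at least 7.53% under each of 5 scalings. A fixed proportion of control RNA in the oxamate+lactate library would give all genes 1 share on the linear scale, while the 7 sterol and fatty acid synthesis genes that were 1.5-fold higher in oxamate had taken back a median of 92.0% (21.2% to 112%), against 44.1% for 913 other such genes. Under the other 3 scalings 4 to 7 such lipid genes had medians of 86.2% to 90.9%, with single genes as low as 8.86%. All 4 medians lay at percentile 100 of random sets, but these lists were picked after they were seen to be lower with lactate. These shares therefore cannot tell a mixture from an effect of lactate. A mixture alone would also keep values between oxamate and control. The whole cholesterol and fatty acid synthesis lists were at 0.23 and 0.09 in oxamate against control. With lactate both lay below control (-0.18, percentile 0.08, and -0.25, percentile 0.02). Values below control are not what a mixture alone gives, but these are the same picked lists, so this does not decide it. For the 2-fold genes the median linear share was 37.3% for those higher in oxamate and 20.4% for those lower. Linear shares move with the scaling: the median of the other 1.5-fold higher genes was 44.1% as deposited and 29.2% with equal sums. A mixture therefore cannot be told apart from an effect of lactate. With 1 library per condition a difference between cultures stays open, and so does noise shared between genes, and an effect of lactate, or of the added sodium, stays open as a hypothesis because no culture had lactate or extra sodium alone.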

How the results depend on the processing

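GC and length removal, shares on the linear scale and the amino acid response list without its 4 lowest members were chosen after seeing the data; the other alternatives were fixed before the data were examined. No paired analysis was possible because each condition has 1 library. The alternative that keeps genes by their counting interval was not run, since whole reads could not be recovered. No list that stood apart reversed its direction relative to random lists, and no named gene that was called changed sign. The lists with at least 5 genes over the floor in use, which can differ from the 28, gave 12 to 14 calls for oxamate against control. They gave 11 to 13 for oxamate+lactate against oxamate and 11 to 13 for oxamate+lactate against control. The settings were a pseudocount of 10, floors of 10 and 200, the mean of a list, 5 matching bins and the GC and length trend removed. The median share taken back lay between 25.5% and 33.0% except where genes were selected on oxamate+lactate against control. The depth is unknown, so what it limits could not be measured. For each count below the cause was not tested, except that other floors and thresholds by construction admit more or fewer genes.

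With a floor of 10, genes higher and lower numbered 550 and 396 for oxamate against control, 45 and 139 for oxamate+lactate against oxamate, and 382 and 373 for oxamate+lactate against control, the overlap was 277 and 196, and 189 genes came halfway back. With no floor these were 808 and 660, 227 and 283, 643 and 609, with an overlap of 439 and 352. With a floor of 200 they were 51 and 36 for oxamate against control and 14 and 10 for oxamate+lactate against control, with an overlap of 12 and 8, and 10 genes came halfway back. At 1.5-fold they were 920 and 489, 31 and 111, 367 and 377, with an overlap of 318 and 265, and 315 genes came halfway back. At 4-fold they were 8 and 7 for oxamate against control, 5 and 1 for oxamate+lactate against control and 0 lower for oxamate+lactate against oxamate, with an overlap of 5 and 1, and 0 genes came halfway back. With a pseudocount of 10, 44 genes were higher for oxamate+lactate against control, 35 were shared and 21 came halfway back.

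Relative to the median ratio, 99 genes were higher for oxamate against control, and 3 higher and 0 lower for oxamate+lactate against oxamate. With equal sums these were 86, 4 and 0, and the median ratio of all genes was -0.022 for oxamate against control and 0.022 for oxamate+lactate against oxamate. Trimmed mean scaling and equal ERCC sums each gave 3 higher and 0 lower for oxamate+lactate against oxamate. With the GC and length trend removed, 82 genes were higher for oxamate against control and 38 for oxamate+lactate against control, 32 were shared and 16 came halfway back. Selection on oxamate+lactate against control gave 0 genes halfway back and a median share of 10.8%.

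Calls of lists lost for oxamate against control were those of T-lineage markers (excess over random lists 0.038 without the GC trend, 0.09 with the mean), endoplasmic reticulum chaperones (0.10, mean), nucleotide synthesis (-0.14, mean) and MondoA targets (-0.16, floor of 200). For oxamate+lactate against oxamate, MondoA targets, mitochondrially encoded genes and endoplasmic reticulum chaperones lost theirs under at least 1 alternative. Without the GC trend, calls were gained by splicing factors (0.16, -0.08 and 0.10 in the 3 comparisons), hyperosmotic response genes (0.35 for oxamate and 0.21 for oxamate+lactate against control) and G2/M genes (-0.06 for oxamate+lactate against oxamate). With the mean in place of the median, cholesterol synthesis genes (0.15) and HIF-1 targets (-0.20) gained calls for oxamate against control. The other calls gained were those of the respiratory chain, HIF-1 targets and T-ALL factors for oxamate+lactate against oxamate, and of hyperosmotic response genes with a floor of 200.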

Other observations

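Lists for other cell types and for histones had fewer than 5 genes over the floor and were not tested. The highest values of their members in any library were 306 for IGLL1 among B-cell markers, 202 for COL1A1 among epithelial and stromal markers, 74 for CD8A among NK-cell and cytotoxic markers, 22 for ITGA2B among erythroid and megakaryocyte markers and 19 for CD68 among myeloid markers. Of the replication-dependent histone genes, whose transcripts lack a poly(A) tail, 9 were in the table and the highest, HIST3H2A, had 60.

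For genes whose mean lay between 50 and 500, the variance between oxamate and control was 7.08 times what counting noise would give if the values were counts. Between oxamate+lactate and control it was 4.59 times, and between the treated libraries 1.78 times. For the 13 ERCC RNAs of that range the same measure was 1.10, 1.94 and 0.748.

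The sodium oxamate medium had no osmotic control, and the test of an osmotic load was chosen after seeing the data. As a hypothesis, sodium oxamate acting as an osmotic load may have raised NFAT5 targets, the genes of the hyperosmotic response. The list of 9 genes over the floor had a median of 0.31 at the 95.1st percentile, inside the range of random lists, and lay at the 99.9th percentile with the GC and length trend removed. It also stood apart with a floor of 200, without that correction (0.25 above random lists). These values leave the hypothesis open, since the call depends on the setting and rests on at most 9 genes.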
